A study of Mus musculus with 18 samples.

How the data were processed

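The series holds 18 samples from C57BL/6 mouse embryonic fibroblasts (MEFs), of which 12 are RNA-seq libraries and 6 are RNA immunoprecipitation (RIP-seq) libraries. For RNA-seq, cells were transfected with a control siRNA or with an siRNA against IMP2, the RNA-binding protein encoded by Igf2bp2, and after 24 h were left untreated or given interleukin-17 (IL-17, 200 ng/mL) for 8 h, per the labels' design text. That gave 4 groups of 3 libraries. For RIP-seq, 3 precipitations with an anti-IMP2 antibody and 3 with control IgG were made from cells given IL-17 at 200 ng/mL for 3 h, per the labels.

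The authors deposited a table of raw read counts per gene for the RNA-seq libraries, with Ensembl gene IDs, symbols and coordinates. The values were whole numbers with different totals per library and were used as counts. The submitters' processing notes name mm10, CASAVA 1.4, STAR and DESeq2, with no role or order, so which step each tool served is not given in the sources used here. RNA-seq libraries were made with Nextera XT and RIP-seq libraries with SMART-Seq v4, per the labels' protocols, and no source used here states strand, so reads of a gene and of an antisense partner, or of near-identical copies, could not be told apart. For RIP-seq only the authors' deposited comparison of IMP2 with IgG was used. It gives, per the file headers, DESeq2's mean normalized count over the libraries compared, the log2 fold change and its standard error, a Wald score equal to the log2 fold change divided by that error (within 8.3e-14), and a p-value with its adjusted p-value. The deposited RIP table held only genes with a log2 fold change of at least 1 and an adjusted p-value of at most 0.05, so genes that failed, or that were lower with anti-IMP2, were not analysed here. A further deposited table lists 97 genes with a signed fold for RNA-seq, a value for RIP-seq and a motif call (Y or N). Its RIP-seq value was 2 times the log2 fold change of the RIP table in 97 of 97 genes (within 1e-06), not 2 to the power of it, and was therefore not read as a fold. A tally of motif calls came with it, and how a motif was called is not given in the sources used here. A sheet of IDs and symbols with no measurement was not used here.

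Counts of the 12 RNA-seq libraries were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (13702 of 48709), libraries were scaled by TMM factors, and a quasi-likelihood model with robust moderation was fitted to all 12 libraries, so that the 4 groups shared 1 estimate of the spread. Library titles carry either the prefix RB160 (4 libraries, 1 per group) or NA (8 libraries, 2 per group). The prefix is balanced over the groups and entered the model as an additive term. What the prefix stands for is not given in the sources used here. The replicate numbers used here only name the libraries: replicate 1 of each group carried the prefix RB160, and replicates 2 and 3 the prefix NA, in the order of their titles. Adjusted p-values are Benjamini-Hochberg values of edgeR's quasi-likelihood test over all genes tested, with a threshold of 0.05. Fold changes are log2 values with a standard error (SE) implied by the quasi-likelihood F statistic, as the absolute log2 value divided by the square root of F. Log2 ratios within a prefix were taken after adding 1 CPM, or 0.1 CPM as an alternative added after the data were seen. Group levels are CPM (counts scaled to a common library total), as mean ± SD of 3 libraries.

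The 5 contrasts were the effect of IL-17 in control siRNA cells and in Imp2 siRNA cells, the effect of Imp2 siRNA without and with IL-17, and the difference of the IL-17 effects (interaction). The pair of IL-17 contrasts shared no library, and neither did the pair of siRNA contrasts. Among 23 gene lists, those with at least 5 tested members were tested against all other genes with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, with an estimated correlation as the alternative and Benjamini-Hochberg adjustment over the lists. Lists that passed camera are called higher or lower as a group. Fry, planned beside camera for direction, asks whether a list moves without setting it against other genes. Its outcome is given for several lists of the Imp2 siRNA comparisons, where it passed lists that camera with an estimated correlation did not. The macrophage, endothelial, epithelial, neural and glial, and erythroid marker lists had fewer tested members, and their genes were described singly. Overlaps of RIP-listed genes with genes changed by Imp2 siRNA were tested with a two-sided Fisher's exact test among genes tested in RNA-seq, and against random gene sets matched on expression by permutation. Which genes could have entered the RIP table is unknown, so this background can hold genes that the RIP-seq libraries could not detect.

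The sample groups, the tests, the gene lists and the rule for named genes were fixed before the data were examined. The named genes were Igf2bp2, the 8 largest rises and 8 largest falls among genes past the threshold with a mean of at least 5 CPM in a group (10 rises for RIP, with a mean normalized count of at least 5), leaving out predicted symbols, up to 4 members of each list with the smallest p, and, for the IL-17 and RIP comparisons, Cebpb, Cebpd, Nfkbiz, Zc3h12a, Lcn2, Il6, Cxcl1 and Cxcl5. Some genes that this rule takes in are not reported here. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these libraries, which may be technical. Depth ranged from 33841054 to 44433699 counts per library, at which a count of 0 allows up to 3 counts. Intervals from counts and binomial intervals (95%, exact) cover counting error only.

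The scripts were tested on simulated counts drawn from the real means, library sizes, fitted dispersions and additive prefix term. Only genes with a mean of at least 1 CPM were changed, and no simulated change differed between prefixes. In the data some effects did differ between prefixes, so the shares recovered can overstate what the fit finds there. With 13543 genes in that step, the fit recovered 84%, 100%, 98% and 100% of changed genes at log2 changes of 0.5, 1, 2 and 3 for the Imp2 siRNA effect with IL-17, with 14 false calls. For the IL-17 effect in Imp2 siRNA cells it recovered 76%, 94%, 98% and 100%, with 8 false calls, and for the interaction 52%, 90%, 96% and 100%, with 8 false calls. Alternatives were DESeq2 1.42.0, other normalizations and filters, no prefix term, a surrogate variable from sva 3.50.0, only the NA libraries, only the groups compared, other thresholds and leaving out each library. A fit with the replicate number as a block, a fit with a cell for each group and prefix, a fit without robust moderation, list tests in reduced fits, a stricter RIP threshold for the overlaps, and ribosomal protein genes without the S6 kinases and Rps19bp1 were added after the data were seen.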

Results

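IMP2 (Igf2bp2) is an RNA-binding protein and reader of the m6A mark on mRNA, and the study asked how it takes part in the response of fibroblasts to IL-17, an inflammatory cytokine. Gene expression was measured in MEFs that received control or Imp2 siRNA, each without or with IL-17 for 8 h, in 3 libraries per group. RNA bound to IMP2 was measured after IL-17 for 3 h, with 3 anti-IMP2 and 3 IgG precipitations. The RNA-seq libraries held 33841054 to 44433699 counts. The largest difference between libraries followed the prefix of their titles: the first principal component (62.1% of the variance) separated the 4 RB160 libraries from the 8 NA libraries, and 9494 of 13702 tested genes differed between prefixes (4767 higher and 4727 lower in RB160). Mitochondrial transcripts took 3.31% to 3.85% of the counts in RB160 and 5.41% to 6.90% in NA libraries. Pairs of NA replicates had reduced chi-square values of 8.67 to 16.02 over genes and pairs across prefixes 156.5 to 219, so no pair agreed within sampling noise. The biological coefficient of variation was 7.95% with the prefix in the model and 28.8% without it.

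**Figure D1:**
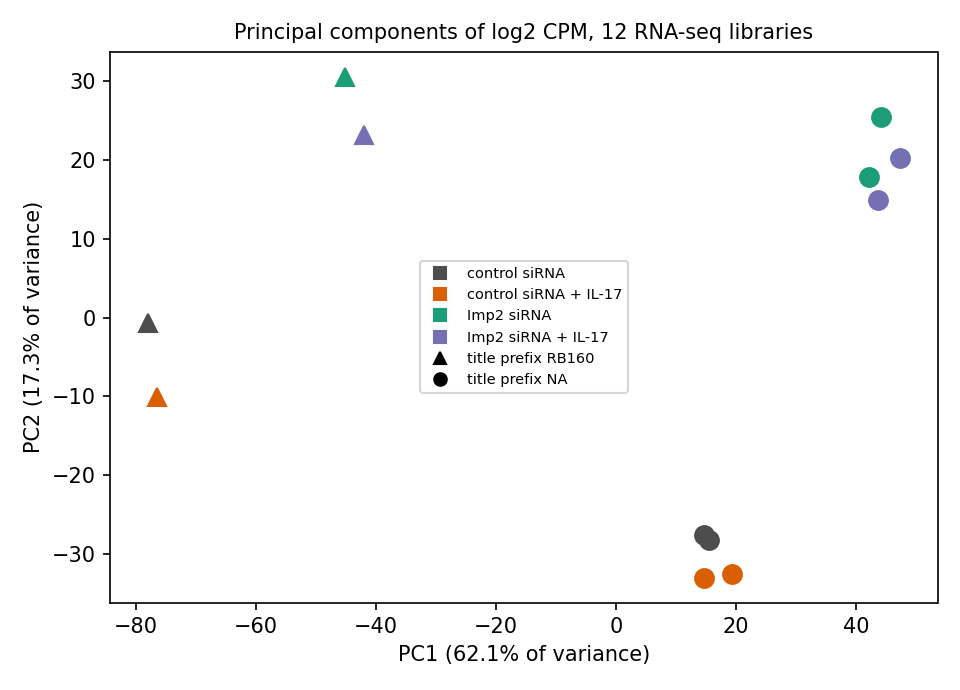
Each point is 1 of the 12 RNA-seq libraries on the first and second principal components of log2 CPM, coloured by group and shaped by title prefix. The first component (62.1% of the variance) parts the prefixes. Within each prefix, both the first and the second component (17.3%) part control from Imp2 siRNA.

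Igf2bp2 itself, the target of the siRNA (ENSMUSG00000033581, chromosome 16, 22059009 to 22163299), was lower in every Imp2 siRNA library than in any control library. It measured 149 ± 17.1 CPM (SD, n = 3) in control siRNA cells and 154 ± 13.5 CPM (n = 3) after IL-17, against 21.9 ± 3.00 CPM (n = 3) and 23.6 ± 4.90 CPM (n = 3) with Imp2 siRNA. The log2 fold change was -2.77 (SE 0.165, adjusted p = 2.71e-06) without IL-17 and -2.70 (SE 0.164, adjusted p = 3.01e-06) with it. Its change with IL-17 did not pass the test, at 0.04 in control and 0.12 in Imp2 siRNA cells.

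Which genes IL-17 changed in control siRNA cells was asked first. Cxcl1, a chemokine that draws neutrophils, rose from 32.3 ± 8.08 to 203 ± 15.9 CPM (n = 3 each; log2 fold change 2.65, SE 0.252, adjusted p = 0.00912). Nfkbiz, which encodes the transcriptional cofactor IκBζ, rose from 31.9 ± 10.4 to 131 ± 30.96 CPM (2.05, SE 0.127, adjusted p = 9.87e-05). Zc3h12a, an endoribonuclease that degrades inflammatory mRNAs, rose by 1.97 (SE 0.236, adjusted p = 0.0166). The largest changes named here and in the later comparisons are those among genes past the threshold with a mean of at least 5 CPM in a compared group. Larger values that did not pass are left out of this order. The other largest rises were in the oxysterol hydroxylase gene Cyp7b1 (1.04), the arginine transporter gene Slc7a2 (1.03), A4galt (0.92), the NF-kB cofactor gene Bcl3 (0.87) and Ier3 (0.74). The largest falls were in the Notch effector gene Hey2 (-0.85), the adrenergic receptor gene Adra1d (-0.79), Enpp5 (-0.62) and Ctnnd2 (-0.59). They were followed by the aggrecanase gene Adamts5 (-0.58), Tmem119 (-0.56), the guidance factor gene Sema3a (-0.55) and Igsf10 (-0.53).

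Of 25 tested IL-17 target genes, 5 rose, 0 fell and 20 did not pass (17 rose when adjusted over the list alone). Besides Cxcl1, Nfkbiz and Zc3h12a, these were Nfkbia, the NF-kB inhibitor IκBα (0.55), and Cxcl5, another neutrophil chemokine, at 0, 3 and 3 counts without and 63, 38 and 31 counts with IL-17 (adjusted p = 0.0162). Of 20 NF-kB subunits and feedback regulators 3 rose (5 adjusted over the list alone), namely Nfkbiz, Nfkbia and Bcl3, and of 13 chemokines 2 rose (6 adjusted over the list alone). The IL-17 target, NF-kB, chemokine and C/EBP family lists were higher as groups, with adjusted p = 0.0266, 0.0266, 0.0447 and 0.0323 with an estimated correlation. No member of the C/EBP family passed the test over all genes (0 of 6, 2 adjusted over the list alone): the values were 0.54 for Cebpb (adjusted p = 0.112) and 1.18 for Cebpd (adjusted p = 0.229), which encode inflammatory transcription factors. Il6 (2.41, adjusted p = 0.125), Lcn2 (2.07, adjusted p = 0.447), Ccl2 (1.54) and Ccl7 (1.39) did not pass either. Lcn2, an antimicrobial protein gene, had 6 counts in the untreated RB160 library but 1568 and 1119 in the untreated NA libraries.

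Vegfa (0.50) was the 1 member of 16 hypoxia and glycolysis genes that rose (4 adjusted over the list alone), and that list was higher as a group at the preset correlation (adjusted p = 3.97e-08, but adjusted p = 0.165 with an estimated correlation). The acute phase list (0 of 9 past, 1 adjusted over the list alone) and the integrated and ER stress list (0 of 16, 0 adjusted over the list alone) were higher at the preset correlation alone, with adjusted p = 0.248 and 0.367 with an estimated correlation. The matrix list (0 of 24, 0 adjusted over the list alone) and the muscle marker list (0 of 6, 2 lower adjusted over the list alone) were lower at the preset correlation alone, with adjusted p = 0.248 and 0.165 with an estimated correlation. The matrix list had a median of -0.13 but a mean of 0.0043. The remaining lists, of interferon-stimulated genes, cell cycle genes, p53 targets, m6A regulators, IMP family targets, the IL-17 receptor pathway, fibroblast markers, mitochondrial mRNAs and ribosomal proteins, did not pass as groups, and no member passed except Zc3h12a in the receptor pathway list. Adjusted over the list alone, 2 IMP family targets fell, 2 fibroblast markers rose and 5 fell, 1 receptor pathway gene rose, and 0 genes passed in the other 6 of these lists.

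In all, 32 genes rose and 24 fell, and 9 of the 56 changed at least 2-fold. All 56, which the pooled test had picked, had the same sign in both prefixes, as did 64.71% of all tested genes, and log2 ratios of all tested genes within RB160 and within NA correlated across genes, which are not independent replicates, at r = 0.48 (rho = 0.407). The count was 1 without the prefix term, when Cxcl1 alone passed, 193 with DESeq2, 152 with the compared groups alone, and 83 without control siRNA replicate 2. It was 13 and 20 without control siRNA replicates 1 and 3, and 6, 18 and 14 without replicates 1, 2 and 3 of control siRNA plus IL-17. The largest count came from the fit with a cell for each group and prefix. The balance of directions moved as well, with 90 rises and 103 falls by DESeq2 and 50 rises and 14 falls in the NA libraries alone.

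**Figure D2:**
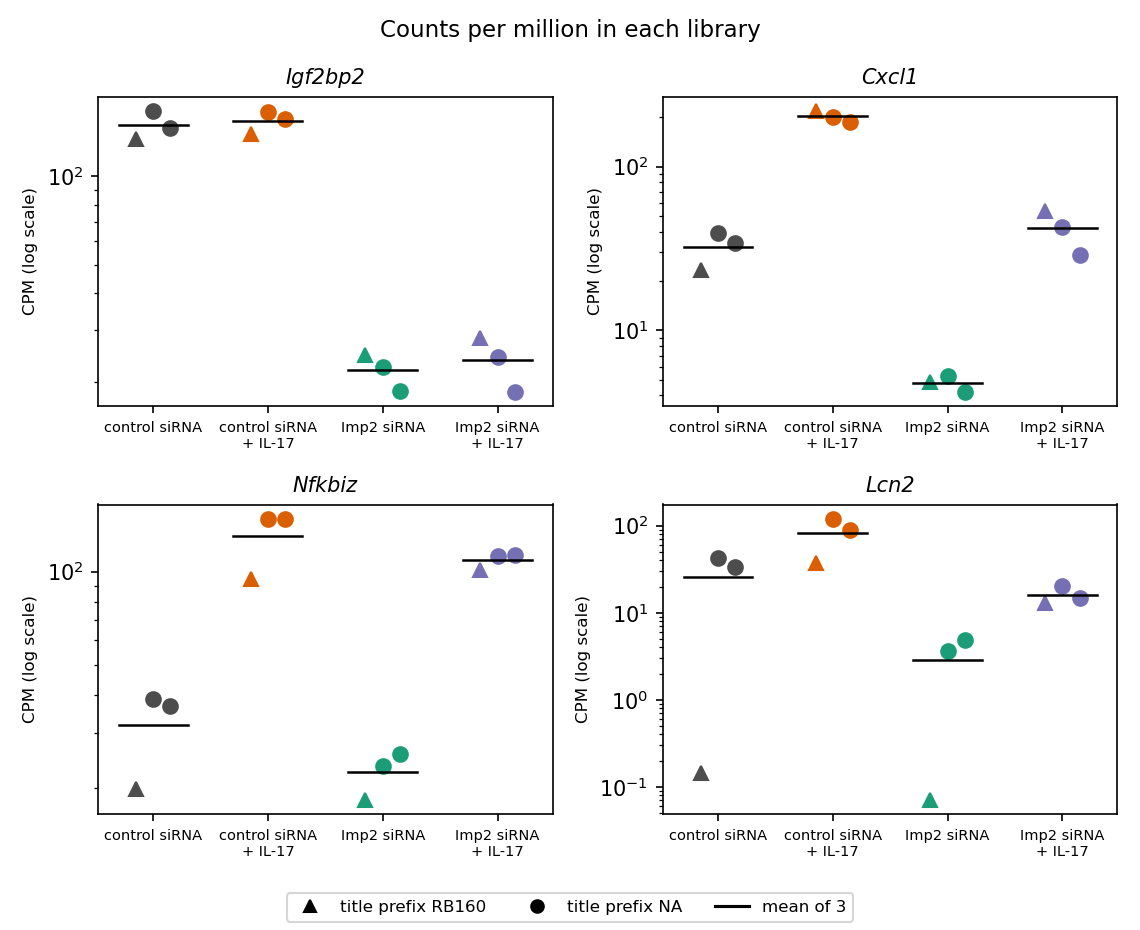
CPM on a log axis of Igf2bp2, Cxcl1, Nfkbiz and Lcn2 in each library of the 4 groups, with triangles for prefix RB160, circles for NA and a line at the mean of 3. Untreated Lcn2 levels lie far apart between the prefixes (6 counts in RB160 control cells, 1568 and 1119 in NA), while Igf2bp2 is lower in all 6 Imp2 siRNA libraries.

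The same comparison in Imp2 siRNA cells asked how cells with less Igf2bp2 mRNA responded. The values used here hold no measure of IMP2 protein. Cxcl1 rose from 4.74 ± 0.519 to 42.0 ± 12.5 CPM (n = 3 each; 3.15, SE 0.295, adjusted p = 0.00738), Nfkbiz from 22.6 ± 3.84 to 109 ± 6.57 CPM (2.30, SE 0.13, adjusted p = 3.85e-05), and Zc3h12a by 2.02 (adjusted p = 0.0103). Among genes past the threshold with a mean of at least 5 CPM, Slc7a2 (1.18), Bcl3 (1.10), Cyp7b1 (0.96), the synaptotagmin gene Syt17 (0.83) and the TGF-beta co-receptor gene Tgfbr3 (0.80) followed. The largest falls were in Adra1d (-0.84), Mrgprf (-0.63), C1qtnf1 (-0.60), Adamts5 (-0.58), Prr5l (-0.58), Tmem119 (-0.56), the Wnt modulator gene Dkk3 (-0.52) and the phosphodiesterase gene Pde8b (-0.49). Of 25 IL-17 target genes 5 rose (13 adjusted over the list alone), among them Nfkbia (0.58) and the chemokine gene Ccl20 (2.56, adjusted p = 0.0368). Ccl20 stayed under a mean of 5 CPM in both Imp2 siRNA groups. Of the NF-kB list 3 of 20 rose (6 adjusted over the list alone), and of the chemokines 2 of 13 (5 adjusted over the list alone). These 3 lists were higher as groups, with adjusted p = 0.0169, 0.0169 and 0.0383 with an estimated correlation. Cebpb (0.16), Cebpd (1.38), Lcn2 (2.89, adjusted p = 0.59) and Il6 (2.05, adjusted p = 0.387) did not pass, and Cxcl5 had 0 counts in all 3 untreated Imp2 siRNA libraries and 3, 5 and 0 after IL-17.

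At the preset correlation alone the acute phase (0 of 9 past, 3 adjusted over the list alone), receptor pathway (1 of 19, 2 adjusted over the list alone) and hypoxia lists (0 of 16, 1 adjusted over the list alone) were also higher, with adjusted p = 0.178, 0.178 and 0.387 with an estimated correlation. The matrix (0 of 24, 1 higher and 1 lower adjusted over the list alone) and muscle marker lists (0 of 6, 0 adjusted over the list alone) were lower in the same way, with adjusted p = 0.28 and 0.338 with an estimated correlation. Here the matrix list had a median of -0.13 but a mean of 0.09. No other list passed, where adjusted over the list alone 1 C/EBP family gene rose, 4 fibroblast markers fell and 0 genes passed in the others. In total 39 genes rose and 23 fell, 12 of them at least 2-fold. All 62, picked by the pooled test on these same libraries, had the same sign in both prefixes, against 58.58% of all tested genes. Log2 ratios of all genes correlated between prefixes at r = 0.455 and rho = 0.293, and at r = 0.303 with a pseudocount of 0.1 CPM in place of 1. Without the prefix term 2 genes passed, Cxcl1 and Nfkbiz, against 171 with DESeq2 and 370 with the compared groups alone. The count was 8, 26 and 20 without replicates 1, 2 and 3 of Imp2 siRNA, and 25, 24 and 43 without those of Imp2 siRNA plus IL-17.

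Whether the response to IL-17 differed between control and Imp2 siRNA cells was tested as an interaction. For Cxcl1 the difference in log2 fold change was 0.50 (SE 0.381), for Nfkbiz 0.25 (SE 0.177) and for Zc3h12a 0.05 (SE 0.326). It was for Lcn2 0.82 (SE 1.36), for Il6 -0.35 (SE 0.777), for Cebpb -0.38 (SE 0.177) and for Cebpd 0.20 (SE 0.452). None passed, each with an adjusted p = 1. By edgeR's quasi-likelihood test 0 of 13702 genes passed, 141 had an unadjusted p under 0.05 where 685 were due by chance, and DESeq2 called 0. With so few small p-values the edgeR test ran conservative here, so 0 calls do not show that the responses were equal. The C/EBP family (adjusted p = 0.0257), integrated and ER stress (0.0054) and hypoxia lists (0.0054) were lower and the mitochondrial mRNAs (0.0342) higher at the preset correlation. With an estimated correlation the adjusted p = 0.635 for the C/EBP family and 0.884 for the other 3, and no member of these lists passed, over all genes or adjusted over the list alone. The pair of IL-17 contrasts shared 25 genes that rose and 11 that fell, against 0.0911 and 0.0403 for independent lists. Their log2 fold changes correlated across all genes at r = 0.435 (rho = 0.479), and at r = 0.964 among the 82 genes past the threshold in either, a set chosen by its size of effect.

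How Imp2 siRNA itself changed the cells was compared without and with IL-17. Without IL-17, the natriuretic peptide gene Nppb rose by 3.77 (SE 0.144, adjusted p = 8.47e-09), the actin nucleator gene Cobl by 3.10, the sarcomere gene Myom1 by 2.67, and the hypoxia-induced gene Ankrd37 by 2.40. Fgf13 (2.36), Siglecg (2.17), Sorbs2 (2.13) and Mmp17 (2.06) rose as well. Besides Igf2bp2, the largest falls included those in the chemokine genes Ppbp (-3.46, SE 0.455, adjusted p = 0.000301) and Cxcl1 (-2.77, adjusted p = 0.000242), and the gelatinase gene Mmp9 (-3.08). They also included the protease inhibitor gene Serpina3g (-2.80), the cytokine gene Tnfsf11 (-2.72) and Slitrk6 (-2.77). With IL-17 the largest rises were again Nppb (3.24), Cobl (2.94), Myom1 (2.58), Ankrd37 (2.37) and Siglecg (2.12), with Lims2 (2.21), the skeletal actin gene Acta1 (2.20) and the nebulin gene Neb (2.14). With IL-17 the largest falls besides Igf2bp2 included those in Serpina3n (-3.57), Ppbp (-3.36), the proteoglycan gene Dcn (-2.83), the enkephalin precursor gene Penk (-2.82), Slitrk6 (-2.72) and the prostaglandin receptor gene Ptgfr (-2.69).

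Of 25 IL-17 target genes, 10 fell and 2 rose without IL-17, and 12 fell and 2 rose with it (adjusted over the list alone, 12 fell and 3 rose, and 13 fell and 2 rose). Cxcl1 (-2.77 and -2.27) and Il1r1 (-1.47 and -1.61), the receptor of IL-1, fell, whereas Tnfaip3 (0.86 and 0.96), an NF-kB feedback inhibitor, and the growth factor gene Csf3 (3.17 and 2.47) rose. Csf3 stayed under a mean of 5 CPM in every group. With IL-17, Cxcl5 had 63, 38 and 31 counts in control and 3, 5 and 0 in Imp2 siRNA cells (adjusted p = 0.000414). Of 20 NF-kB genes 12 fell and 2 rose without and 14 fell and 2 rose with IL-17 (13 and 14 fell and 2 and 2 rose adjusted over the list alone), among them Nfkbie (-0.83 and -0.79). Of 13 chemokines 6 and 7 fell (7 and 7 adjusted over the list alone), with Ccl9 at -1.27 and -1.21. Of 9 acute phase genes 5 and 5 fell (adjusted over the list alone, 6 fell and 0 rose, and 7 fell and 1 rose), including C3 (-1.77 and -1.64) and Cp (-2.13 and -1.95). These 4 lists were lower as groups at the preset correlation. With an estimated correlation, however, camera gave adjusted p = 0.672, 0.243, 0.356 and 0.356 without and 0.612, 0.214, 0.477 and 0.477 with IL-17. By fry the NF-kB, chemokine and acute phase lists passed in both comparisons and the IL-17 target list in neither. In the C/EBP family, Cebpd fell in both (-1.50 and -1.31), Cebpb fell with IL-17 (-0.57, adjusted p = 0.00367) but did not pass without it (-0.19, adjusted p = 0.276), and Ddit3 (0.65 and 0.60) and Cebpg (0.44 and 0.34) rose. That list had 2 rises and 1 fall without and 2 rises and 3 falls with IL-17, the same numbers adjusted over the list alone, and did not pass as a group, with a median of -0.04 and a mean of -0.12 but an upward test direction without IL-17. Nfkbiz fell without IL-17 (-0.47) and did not pass with it (-0.22). No gene, Cebpb and Nfkbiz included, passed the edgeR interaction test. A pass in only 1 of the siRNA comparisons, here or below, therefore does not show that the siRNA effect depended on IL-17.

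Fibroblast markers fell and smooth muscle markers rose. Pdgfra (-2.23 and -2.31), Dcn (-2.65 and -2.83), Prrx1 (-0.89 and -0.93) and Pdgfrb (-0.50 and -0.50) were among 7 of 11 fibroblast markers that fell in each comparison, while 1 rose (7 and 1 adjusted over the list alone; adjusted p = 0.0237 without and 0.0531 with IL-17 with an estimated correlation). Cnn1 (1.38 and 1.49), Acta2 (1.01 and 1.08), Tagln (0.89 and 0.93) and Myh11 (2.64 and 2.61), genes of contractile cells that activated fibroblasts also express, were among 4 and 5 of 6 muscle markers that rose (5 and 6 adjusted over the list alone; adjusted p = 0.0237 and 0.0266 with an estimated correlation). Myh11 stayed under a mean of 5 CPM in every group, so its large change is one of a gene with a low level. The basement membrane genes Col4a1 (0.73 and 0.77) and Col4a2 (0.71 and 0.76) rose and Col3a1 (-0.72 and -0.85) and Mmp9 fell. The matrix list as a whole went both ways, with 9 and 9 rises and 7 and 6 falls of 24 (the same adjusted over the list alone), a median of 0.03 and a mean of -0.27 without IL-17.

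Markers of other cell types were also examined. Of 4 tested epithelial markers, Krt8 (1.72 and 2.62) and Krt19 (0.73 and 0.63) rose in both comparisons, Krt18 rose with IL-17 (1.34) and Cdh1 fell (-1.15 and -1.25). Krt19 averaged 111 CPM over the 12 libraries, while Krt8 stayed under a mean of 5 CPM in both groups given IL-17. Of 4 macrophage markers, Mrc1 fell (-3.00 and -1.41), as did Cd14 with IL-17 (-0.67), the list's most abundant member at 6.87 CPM. Of 3 endothelial markers Cdh5 fell without IL-17 (-1.64), and the most abundant, Egfl7, stood at 3.16 CPM. Of 4 neural and glial markers Stmn2 fell in both (-0.74 and -0.64) and Map2 without IL-17 (-0.74), and the most abundant, Tubb3, stood at 42.1 CPM. Erythroid markers had 0 tested members, and Alas2, the most abundant, was at 0.0447 CPM. No member of these 5 lists passed in either IL-17 comparison.

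Among p53 targets 9 and 9 of 14 rose and 1 and 1 fell (9 and 10 rose and 1 and 1 fell adjusted over the list alone). The cell cycle inhibitor gene Cdkn1a stood at 0.54 and 0.61 and the apoptosis gene Bbc3 at 0.80 and 0.72. Hypoxia and glycolysis genes rose in 11 and 8 of 16, and 0 and 1 fell (13 and 10 rose and 1 and 1 fell adjusted over the list alone), with the prolyl hydroxylase gene Egln3 at 1.51 and 1.15 and Aldoa at 0.54 and 0.50. Integrated and ER stress genes rose in 8 and 6 of 16 (8 and 7 adjusted over the list alone), with Atf4 at 0.51 and 0.44 and Sesn2 at 0.61 and 0.66. Replication genes such as Mcm2 (-0.46 and -0.40), Pcna (-0.41 and -0.37) and Tyms (-0.65 and -0.75) were among 10 and 10 of 25 cell cycle genes that fell (10 and 11 adjusted over the list alone). Interferon-stimulated genes fell in 8 and 5 of 20 (8 and 5 adjusted over the list alone), with Gbp2 at -1.58 and -1.50 and Bst2 at -0.59 and -0.50. All 5 lists passed camera at the preset correlation, and fry, in both comparisons, but none passed camera with an estimated correlation. There, camera gave adjusted p = 0.106, 0.356, 0.356, 0.511 and 0.356 without IL-17 and 0.0702, 0.477, 0.55, 0.531 and 0.477 with it.

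Among 20 m6A regulators, the methyltransferase gene Mettl3 (-0.60 and -0.60) and the IMP2 paralogue Igf2bp3 (-0.40 and -0.40) fell and the demethylase gene Alkbh5 rose (0.29 and 0.22), with 2 and 2 rises and 5 and 7 falls in all (the same adjusted over the list alone), 1 of the falls in each being Igf2bp2, the target of the siRNA. Of 18 known IMP family targets 4 and 3 rose and 3 and 2 fell (the same adjusted over the list alone), among them the noncoding RNA H19 (-2.14 and -2.46). The IL-17 receptor pathway had 6 and 6 rises and 2 and 2 falls of 19 (6 and 6 rises and 3 and 2 falls adjusted over the list alone), with the adaptor gene Tab2 at 0.40 and 0.39 and the receptor gene Il17rd at -0.77 and -0.65. Of 92 ribosomal protein symbols 4 and 5 rose and 7 and 10 fell (1 and 3 rose and 5 and 7 fell adjusted over the list alone), and of 13 mitochondrial mRNAs 0 passed in either comparison (0 adjusted over the list alone). None of these lists, nor the matrix list, passed camera as a group. By fry the m6A list was lower (adjusted p = 0.00911 without and 0.00652 with IL-17). The receptor pathway list was higher by fry with IL-17 (adjusted p = 0.0336) but did not pass without it (adjusted p = 0.132). The others did not pass by fry.

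**Figure D3:**
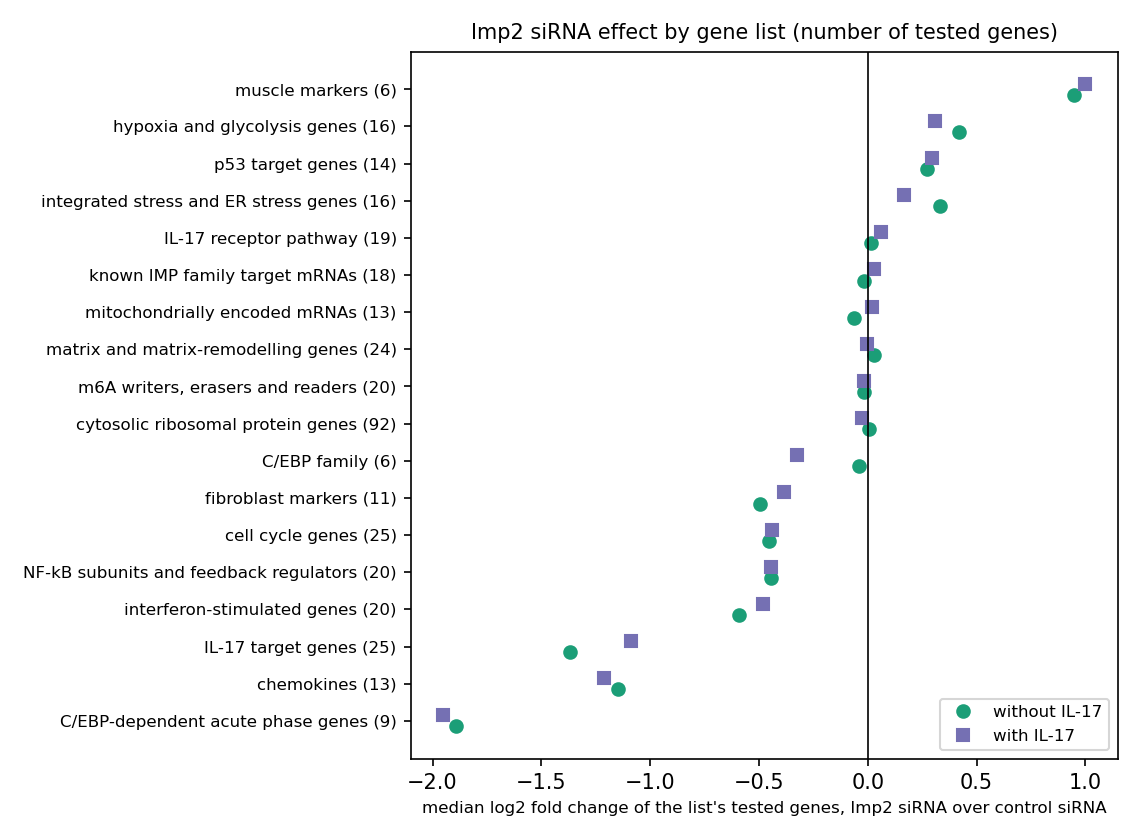
Median log2 fold change of the tested members of each gene list, Imp2 siRNA over control siRNA, without IL-17 (circles) and with IL-17 (squares), with the number of tested genes in brackets. Medians run from -1.95 for acute phase genes to 1.00 for muscle markers, both with IL-17.

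Altogether 2205 genes rose and 2241 fell without IL-17, and 2288 rose and 2270 fell with it; at 2-fold or more these were 264 and 381, and 274 and 405. Both comparisons shared 1820 rises and 1802 falls, against 368 and 371 for independent lists, and their log2 fold changes correlated across genes at r = 0.834 (rho = 0.846). Of the called genes, 4408 of 4446 and 4532 of 4558 had the same sign in both prefixes, against 72.53% and 72.64% of all tested genes. The pooled test on these same libraries had picked the called genes, which favours such agreement. Within-prefix log2 ratios correlated across all genes at r = 0.681 and 0.688 (rho = 0.634 and 0.644). Without the prefix term 303 and 318 genes passed, and with the NA libraries alone 4172 and 4289.

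RNA bound to IMP2 was asked of the RIP-seq. The authors' deposited table listed 5294 genes enriched with anti-IMP2 over IgG, with a median log2 fold change of 2.16, and 3040 of them were at 2 or more. Among the fixed genes, the authors' deposited table gave Cxcl1 a log2 fold change of 3.58, Cebpd 1.97, Igf2bp2 itself 1.94, Il6 1.75, Zc3h12a 1.71, Cebpb 1.56 and Nfkbiz 1.196, and did not list Lcn2 or Cxcl5. The largest values in the authors' deposited table were for Zfp938 (6.31), Rps24-ps3 (6.18), Tmem256 (5.97), the small noncoding RNA Bc1 (5.77), Ndufb4c (5.59), the nucleosome-binding protein gene Hmgn3 (5.47), Rps27rt (5.46), Hmga1b (5.30), the noncoding RNA Zfas1 (5.27) and Rpl34-ps1 (5.21). Several of these are near-identical copies or pseudogenes of other genes, so which copy the reads came from is uncertain. Ribosomal protein genes were listed in 83 of 92 cases, against 52.5 in expression-matched sets (permutation test, adjusted p = 0.0036 from a raw p of 2e-04, the smallest the permutations can give), and in 80 of 83 without the S6 kinases and Rps19bp1 that the name pattern took in. Chemokines were listed in 9 of 13 (3.86 matched, permutation test, adjusted p = 0.011) and matrix genes in 4 of 24 (11.5 matched, permutation test, adjusted p = 0.011). Gene span is the distance from a gene's start to its end coordinate, introns included, and is not the length of its mRNA. In a logistic model of listing on expression bin and gene span, added after the data were seen, chemokines did not pass (log odds 1.83, SE 1.13, z = 1.62). Ribosomal protein genes (1.15, SE 0.405) and matrix genes (-1.46, SE 0.588) did. The other 15 lists did not pass, with 7 of 25 IL-17 targets, 4 of 6 C/EBP family members and 5 of 18 known IMP family targets listed. Listing rose with expression, from 1.60% of genes in the lowest of 20 expression bins to 60.5% in the highest.

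Genes of the RIP table were then set beside those changed by Imp2 siRNA, among 4721 listed genes tested in RNA-seq. The conditions differed: all RIP-seq cells had IL-17 for 3 h, while RNA-seq cells had it for 8 h or not at all. With IL-17, 777 listed genes fell (odds ratio 0.988, two-sided Fisher's exact test, p = 0.809) and 894 rose (odds ratio 1.27, p = 4.64e-07). Without IL-17, the same two-sided Fisher's exact test gave 732 that fell (odds ratio 0.909, p = 0.0519) and 875 that rose (odds ratio 1.31, p = 2.38e-08). Against random sets matched on expression the direction for rising genes turned: the observed overlap was 0.927 times the matched one with IL-17 (permutation p = 0.002) and 0.948 times without (permutation p = 0.02), and for falling genes it was 0.957 (permutation p = 0.081) and 0.913 (permutation p = 0.001, the smallest the permutations can give). At 4 other thresholds the matched ratio for falling genes with IL-17 passed (0.907 to 0.957, permutation p = 0.01 to 0.034). That for rising genes without IL-17 did not pass at a RIP adjusted p under 0.01 (0.961, permutation p = 0.11). As a set, the listed genes did not move against all other genes (camera p = 0.335 without and 0.451 with IL-17, and p = 0.426 and 0.54 with an estimated correlation). The deposited RIP log2 fold change and the siRNA effect with IL-17 correlated across 4721 genes at r = 0.014 (rho = 0.026). The authors' deposited table of 97 genes does not name the contrast of its RNA-seq folds, each at least 2 in size. These folds matched the siRNA effect with IL-17 in sign in 97 of 97 genes (r = 0.998 on the log2 scale across genes), and the effect without IL-17 in 97 of 97 as well (r = 0.989). The median log2 difference was 0.032 with and 0.109 without IL-17, so the folds lay closer to the effect with IL-17. Both sides rest on the RNA-seq of this series, so the match only helps to name the contrast. Of these folds 59 were negative and 38 positive. Of those 97 genes, 36 carried a motif call of Y in the authors' deposited table, 22 with a negative and 14 with a positive fold (Fisher's exact test, two-sided, p = 1), and in the authors' tally 2077 of 5294 enriched genes did (39.2%, exact binomial interval 37.9% to 40.6%), and 1801 of 4933 annotated ones (36.5%). The tally's cells for unannotated genes (361 and 85) did not add up with these as labelled, but did if read as the total and the count with no motif.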

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

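The fit with a cell for each group and prefix was chosen after the results were seen. The sets matched on expression were planned, but what they would show if expression level were the cause was written after their result was seen. The test of other splits was planned. Effects were compared between the prefixes RB160 and NA because genes of the same contrast moved by different amounts in the libraries of each. The lone RB160 library of each group was assumed to vary like the NA pairs. The test of the difference between prefixes passed for 15 genes for IL-17 in control siRNA cells, 7 for IL-17 in Imp2 siRNA cells, 156 for Imp2 siRNA without IL-17, 212 for Imp2 siRNA with IL-17 and 2 for the interaction.

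The genes that follow were chosen after their values were seen. Each RB160 value set 1 library against 1, so a difference between prefixes could not be separated from one of single libraries. With IL-17 in control siRNA cells, Selp, an adhesion receptor gene, had 2.75 in RB160 and 1.12 in NA (difference adjusted p = 0.000213), Zc3h12a 2.66 and 1.70 (0.0233), and C3 1.53 and 0.35 (0.00591). In Imp2 siRNA cells IL-17 gave Selp 2.63 in RB160 and 0.98 in NA (difference adjusted p = 2e-04) and Zc3h12a 2.64 and 1.71 (0.0355). Has2, a hyaluronan synthase gene, had Imp2 siRNA values of 0.82 without and 0.48 with IL-17 in RB160 and -0.98 and -0.99 in NA, with difference adjusted p = 4.26e-06 and 2.28e-05. The chemokine gene Ccl7 had -1.09 and -0.55 in RB160 and -2.52 and -2.001 in NA. The 2 interaction genes were Gm14434 and Gm20458, which carry predicted symbols.

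Lcn2 stood at 6 counts in the untreated control library with prefix RB160 and at 1568 and 1119 counts in those with prefix NA. The 3 Imp2 siRNA libraries given IL-17 had 583, 673 and 467. RNA or reads from IL-17-treated cells in the untreated NA libraries would leave every IL-17-induced gene with at least the untreated to treated ratio of Lcn2 (0.363). Of 23 genes compared, 3 lay below it beyond counting error, with Cxcl1 at 0.189, Nfkbiz at 0.255 and Zc3h12a at 0.308. That argues against such mixing as the whole cause and leaves a smaller share open. A higher baseline of IL-17 target genes in the NA cells may be part of it, since 20 of the 24 other members were higher in NA (median 1.30), but camera with an estimated correlation gave p = 0.0579, so this could not be decided with 1 RB160 library. In the acute phase list, which also holds Lcn2, only 4 of the 8 other members were higher in NA (median -0.18). No other biological explanation was tested, as the labels give no group for the prefixes.

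Genes bound to IMP2 were over-represented among genes that rose with Imp2 siRNA under IL-17. Gene span as the whole cause was argued against, because the overlap was 1.16 times that of random sets matched on span (permutation p = 0.001, the smallest the permutations can give). Expression level is a candidate explanation: against sets matched on expression the ratio was 0.927, so nothing of the excess was left. Whether IMP2 binding itself changes the level of its targets stays open, since which genes the RIP-seq could detect is unknown. Binding was also measured at 3 h of IL-17 and RNA levels at 8 h.

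For the split of 3 against 3 libraries, 10 splits are too few for a share under 0.05 in each of the 4 comparisons, where 1 split, the real one, gave as many genes. For IL-17 in control siRNA cells the real split gave 56 genes and the highest other 49, for IL-17 in Imp2 siRNA cells 62 and 0, and for Imp2 siRNA without and with IL-17 4446 and 0, and 4558 and 0. The split with 49 genes set control siRNA replicates 1 and 3 and control siRNA plus IL-17 replicate 3 against the rest. For the interaction 40 of 40 regroupings gave as many as the real 0, which any count does, so this decided nothing. The highest other gave 2900, which points to a structure of the samples. It held 5 Imp2 siRNA libraries among the 6 that the contrast adds, but 3 regroupings as uneven gave 0, so what set it apart stays open.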

How the results depend on the processing

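The replicate block, the smaller pseudocount, the fit with group by prefix cells, the fit without robust moderation, the list tests in reduced fits and the RIP threshold of 0.01 for the overlaps were chosen after the data were seen. Igf2bp2 fell past the threshold in every alternative run, with log2 values from -2.94 to -2.67 without and -2.92 to -2.54 with IL-17. For IL-17 in control siRNA cells, where 56 genes passed, and in Imp2 siRNA cells, where 62 passed, the counts were 92 and 111 at an adjusted p under 0.1, and 9 and 12 at 2-fold. They were 95 and 110 with no filter, and 1 (Cxcl1) and 2 (Cxcl1 and Nfkbiz) without the prefix term. A surrogate variable gave 91 and 109. They were 152 and 370 with the compared groups alone, 193 and 171 with DESeq2, and 618 and 377 with group by prefix cells. Leaving out a library gave 6 (without control siRNA plus IL-17 replicate 1) to 83 (without control siRNA replicate 2) and 8 (without Imp2 siRNA replicate 1) to 43 (without Imp2 siRNA plus IL-17 replicate 3). The other libraries gave 13, 20, 18 and 14 for control siRNA replicates 1 and 3 and control siRNA plus IL-17 replicates 2 and 3, and 26, 20, 25 and 24 for Imp2 siRNA replicates 2 and 3 and Imp2 siRNA plus IL-17 replicates 1 and 2. For Imp2 siRNA without and with IL-17, 645 and 679 passed at 2-fold and 303 and 318 without the prefix term. Leave-outs gave 3169 to 4039 and 3313 to 4099. The interaction stayed at 0 by edgeR (141 at an unadjusted p under 0.05) and DESeq2 and in every leave-out, and was 1 with group by prefix cells (Gm14434, chosen after its values were seen). Lists past camera numbered 4, 3, 2, 1 and 0 with an estimated correlation, in the order of the 5 contrasts, against 9, 8, 11, 11 and 4. Leaving out a library gave 8 to 14 lists (14 without control siRNA replicate 1) for IL-17 in control cells, 4 (without Imp2 siRNA replicate 1) to 12 (without Imp2 siRNA replicate 2) in Imp2 siRNA cells, and 2 (without replicate 1 of either IL-17 group) to 7 (without control siRNA replicate 1) for the interaction. The correlation of IL-17 effects went from 0.435 to 0.964 among genes past the threshold in either, a set picked by size. The odds ratio for bound genes that fell without IL-17 passed at 0.889 (siRNA adjusted p under 0.1), 0.888 (unadjusted p under 0.05) and 0.853 (RIP log2 of at least 2), as did the ratio to expression-matched sets, 0.913. For genes that rose, the matched ratios reversed the direction, at 0.948 without and 0.927 with IL-17. A stricter threshold lowers a count by construction, and for the other changes the cause was not tested. Named genes lost a call in 88, 66, 64 and 65 and gained one in 44, 47, 1 and 6 of the alternatives for the first 4 contrasts, with 0 reversed. Values past no threshold changed sign in 17, 8 and 1 for the first 3 and in 46 for the interaction. RIP tests from counts (DESeq2, RLE, library size, filters, leave-outs, camera) were not run, since only the authors' comparison was used, and neither was a pseudocount for the tests, since counts were at hand. With 0.1 CPM in place of 1 CPM, log2 ratios correlated between prefixes at r = 0.327, 0.303, 0.593 and 0.612 for the first 4 contrasts, and as many called genes had the same sign in both. RIP at any positive fold is the same set, and the interaction already used all groups. With a replicate block (the numbers, which follow title order) the counts for the 5 contrasts were 77, 73, 4672, 4791 and 0, and 10, 8, 11, 11 and 4 lists passed. The labels do not say that the numbers pair libraries. Between NA replicates 2 and 3, deviations correlated over 0.1 in 3 of 6 pairs of groups (r = 0.017 to 0.166), and 9 of 12 libraries, prefix included, correlated best with their own number in all other groups. For RIP no paired analysis was possible because the values used hold no samples.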

Other observations

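The comparisons of baseline levels between prefixes, of genes raised by IL-17 under Imp2 siRNA and in RIP, and of expression level as a source of short spans were chosen after the results were seen. Among untreated control libraries, 1 of 20 interferon-stimulated genes was higher in NA than in the RB160 library, and their median log2 difference (-1.72) was the largest in size of 18 lists. This compared 2 libraries with 1, so a difference between prefixes could not be separated from that 1 library.

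Of the 25 genes that rose with IL-17 in both siRNA groups, 15 fell and 1 rose with Imp2 siRNA without IL-17 (median log2 -0.47), and 15 fell and 3 rose with it (median log2 -0.44). Over all 13702 tested genes, 2241 fell and 2205 rose without IL-17, and 2270 fell and 2288 rose with it. The 25 genes were picked by comparisons that use the same libraries, and this difference was not tested. The authors' deposited table listed 11 of these 25 as bound, and 4 of the 11 that fell with IL-17 in both. Among all 13702 tested genes 4721 were listed, and the share rose with expression to 60.5% in the highest bin. The share due for genes of the same expression as these was not computed and no test was made. These counts therefore show neither an excess of bound genes nor its absence.

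Genes listed as bound to IMP2 in the authors' deposited table lay in short spans, with a median of 15.9 kb against 35 kb for other genes in the same expression bins (5 to 20 of 20). In 16 of these 16 bins the listed genes were shorter, which argues against expression level as the whole cause, and without ribosomal protein genes and pseudogenes it was again 16 of 16 (16.3 against 35 kb). Genes of short span may be favoured by binding or by the RIP-seq itself, and no value used here decides between these. Transcript length was not measured here. With span in the model the log odds of listing went from 2.09 (SE 0.36) to 1.15 (SE 0.405) for ribosomal protein genes and from -1.72 (SE 0.567) to -1.46 (SE 0.588) for matrix genes. For chemokines they went from 2.71 (SE 1.10) to 1.83 (SE 1.13), which no longer passed, as the estimate fell while its error hardly changed.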
